A study of Rattus norvegicus with 18 samples.

How the data were processed

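RNA from brain cortex of 18 male rats was measured on 1-colour 60-mer rat oligonucleotide arrays (41012 probes on 43379 spots, and 1639 control spots), 1 animal per array, on 5 slides scanned on 2 days. The deposited raw files, written by Agilent Feature Extraction 9.1.1.1, give per spot a processed signal (background-subtracted intensity, per the file headers in linear units) together with the spot's quality calls. The authors' deposited value table gives log2 signal intensity per probe; it was checked against the raw files and equals the mean log2 processed signal without scaling between arrays (largest difference 5.3e-14). The dose of EPO is not in the labels. Groups were taken from the labels, and each holds 3 arrays, so the number of arrays limits the precision.

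Spots of the same probe (263 probes have several) were averaged on the log2 scale after leaving out spots that the software had marked as outliers, and the 75th percentile of each array was subtracted. Probes well above background on every array of at least 1 group were tested, 28634 in all, and 345 probes that lost all spots on some array were left out. Probes were named from the annotation of rat transcripts by accession (10735), symbol (5571) or synonym (3729), and the others kept only the name in the file. For gene-level work the probe of highest mean signal stood for its gene (12391 genes). Where every array of the lower group was below background, a bound on the fold is given. It sets the brighter group's mean against the higher of the probe's own signal and the lowest signal called well above background on each array of the dimmer group. Changes of probes dim on part of the arrays are given on the log2 scale only.

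Comparisons were fitted with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8, and statmod, version 1.5.0). It was 1 model of group means over all 18 arrays, 12 residual degrees of freedom, moderated two-sided tests, and Benjamini-Hochberg adjustment over the probes tested at 0.05. The comparisons were ischemia against sham, EPO against saline in ischemia and EPO-treated ischemia against sham at each time, sham at 6 h against 2 h, and the interactions of ischemia and of EPO with time. The 31 gene lists (18 of pathways and 13 of cell types) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 31 lists within each comparison. Camera sets a list against all other genes, and fry's directional p asks whether a list's genes moved one way on balance. The activity-regulated plasticity list was written partly from memory of the published study of these samples. The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, apart from the alternatives that use the spike-in slope and the tests that the later parts name as chosen afterwards.

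By that rule each main comparison names, among gene symbols past the threshold whose groups do not overlap, the 8 largest rises and the 8 largest falls, the other comparisons 5 of each, and where none passes the 5 of smallest p in each direction. It also names up to 4 members of smallest p per list, leaves out symbols that are only locus or accession names, and in every case gives Epo, Epor, Bdnf, Arc, Egr1, Fos, Hspa1b, Il1b, Ccl2 and Gfap. Some genes that the rule names are not reported here. Reversal was tested on the genes called in ischemia at each time, in the EPO comparison at the other time, which shares no array. Sharing of calls between ischemia with saline and with EPO was set against simulated groups that did not differ but shared a simulated sham group. These groups were drawn at random from the residuals of all arrays, whatever their group or time.

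Replicate numbers were checked for pairing. Only between EPO and saline at 2 h did every same-number pair correlate above 0.1 across probes (0.887, 0.654 and 0.635). In both of these groups replicate 1 was the array with a spike-in slope above 0.9, and EPO replicate 3 correlated best with another number. These correlations therefore do not establish pairing. A fit with the replicate number as a block also called 0 probes for EPO at 2 h (360 at an unadjusted p under 0.05 in limma). Slides, arrays with title numbers apart from the others, saturated spots, the background correction, the filter, the normalization, the variance model, the threshold and the arrays in the fit were varied 1 at a time, and each array was left out in turn. After the spread of the spike-in slopes had been seen, 3 more alternatives used it: the class above and below 0.9 as a block, the slope as a covariate, and a fit without the 6 steep arrays.

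The procedure was tested on simulated data with independent normal noise of each probe's own spread and 200 changed probes per run in 5 runs. For ischemia at 6 h it recovered 44.0%, 64.0%, 84.0% and 90.8% of changes of 1.5, 2, 4 and 8-fold, with 6.6 false calls per run on average, and for EPO at 6 h 50.8%, 67.2%, 84.4% and 88.4%, with 8.0 false calls. It made 0 calls in limma where nothing had been changed. A list shifted by 0.5 on the log2 scale was called in 5 of 5 runs, and 0 of 145 tests of other lists were called. Independent noise leaves out the correlation between genes in the real arrays. These runs therefore do not measure how often lists or probes are falsely called in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.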

Results

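Gene expression was measured in brain cortex of male rats of the Crl:CD(SD)BR strain by hybridizing each animal's RNA to its own 1-colour oligonucleotide array. The 18 arrays form 6 groups of 3: sham-operated rats, rats with cerebral ischemia given saline, and rats with ischemia given erythropoietin (EPO), each group at 2 h and at 6 h. Ischemia was made by occluding the middle cerebral artery, which feeds much of the lateral cortex. EPO is the hormone that drives red cell formation and has been studied as a protector of neurons. Values below are log2 signal relative to the 75th percentile of the array, changes are log2 differences ± the standard error of the fit, and every group holds n = 3 arrays unless stated. The number of arrays limits the precision: the median standard error of a log2 change over the 28634 probes tested was 0.13.

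Signal quality differed between arrays, and not only by group. Between 61.5% and 80.6% of the 41012 probes were well above background. The slope of log signal on log amount of the spiked-in viral transcripts parted the arrays into 6 with slopes of 0.914 to 0.941 and 12 with slopes of 0.788 to 0.866. The 6 steep arrays had 61.5% to 66.4% of probes well above background and the other 12 had 68.6% to 80.6%. Steep arrays numbered 0 in sham at 2 h, 2 in ischemia with saline at 6 h and 1 in each of the other groups. They were all 4 arrays of slide 5, the only slide scanned on a second day, and 1 array each on slides 1 and 2, beside arrays of the other class. The first principal component, with 74.9% of the variance, parted the same classes, and the second held 7.03%. Correlations across probes between pairs of arrays ran from 0.926 to 0.993.

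**Figure D1:**
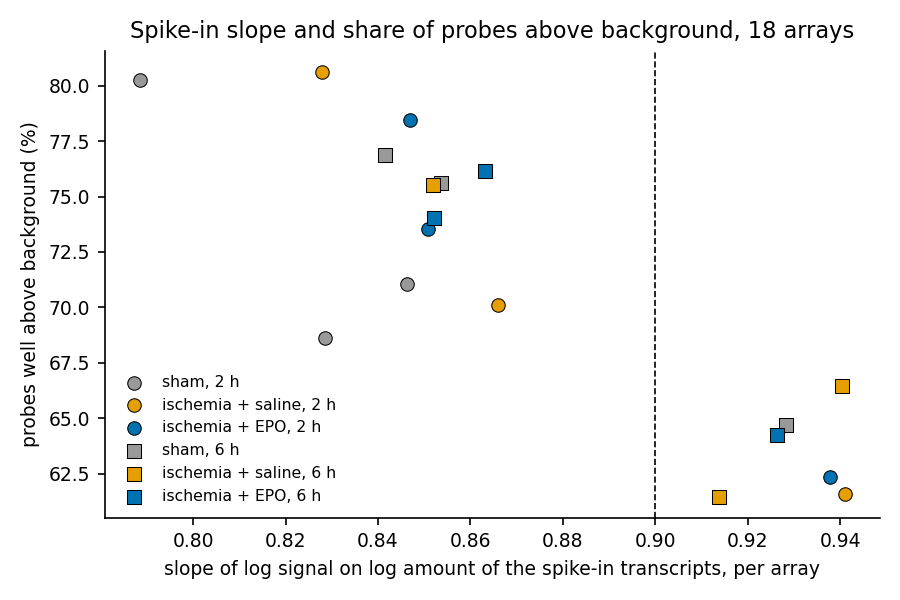
Each point is 1 of the 18 arrays, with the slope of log signal on log amount of the spike-in transcripts on the x axis and the percentage of probes well above background on the y axis; colour gives the treatment, and circles are 2 h and squares 6 h. The dashed line at 0.9 parts the 6 steep arrays, at 61.5% to 66.4%, from the other 12, at 68.6% to 80.6%.

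The first question was what ischemia does to cortical gene expression within 2 h. Stress, chemokine and immediate-early genes rose far above sham. Hspa1a (probe A_44_P1042876), the stress-inducible HSP70 chaperone, was 44.2-fold higher (5.46 ± 0.17, adjusted p = 2.0e-09). The neutrophil-attracting chemokines Cxcl1 (probe A_42_P473398) and Cxcl2 rose by 5.48 ± 0.33 and 5.18 ± 0.33; no sham array read either above background, so these are at least 19.5-fold and 13.2-fold changes. Ccl3, a chemokine for macrophages, was 40.8-fold higher (5.35 ± 0.36), and Ccl2 (probe A_42_P695401), a chemokine for monocytes, rose by 3.64 ± 0.36 with 1 of 3 sham arrays above background. Among transcription factors of early responses, Atf3 was 29.9-fold higher (4.90 ± 0.37), Fos (probe A_44_P495480) 13.5-fold (3.76 ± 0.31), and Npas4, which neuronal activity switches on, rose by 4.57 ± 0.50 with 1 of 3 sham arrays above background.

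The falls at 2 h were much smaller. Fmo2, a flavin monooxygenase, fell by 1.06 on the log2 scale, Srarp, a steroid receptor partner, by 1.01, and Sox18, an endothelial transcription factor, by 0.97. Mrpl41, a protein of the mitochondrial ribosome, fell by 0.83, C15h8orf58 by 0.73, and Degs2 (probe A_44_P375502), an enzyme of sphingolipid synthesis, by 0.71. Pdzd4, at -0.69 ± 0.15, passed in 7 of 22 alternative analyses, and Tecpr2, at -0.68 ± 0.13, in 12 of 22. The neurotrophin Bdnf (probe A_44_P219026) rose by 1.51 ± 0.20, the synaptic plasticity gene Arc (probe A_44_P118724) by 2.69 ± 0.24, Egr1 by 1.60 ± 0.14 and the cytokine Il1b (probe A_44_P230320) by 1.90 ± 0.29. Gfap, the astrocyte filament, was at 0.02 ± 0.18 and the EPO receptor Epor at -0.36 ± 0.34, and neither passed the test (adjusted p = 0.971 and 0.654).

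Of the fixed gene groups, immediate-early genes moved most at 2 h: 23 of 28 measured members rose, 25 when adjusted over the list alone, with a median of 1.68 (adjusted p = 1.0e-56). Nr4a2 rose by 1.19 ± 0.09, Ier2 by 1.85 ± 0.15 and Dusp1 by 1.76 ± 0.14. Activity-regulated plasticity genes rose in 17 of 27, 20 when adjusted over the list alone (median 1.03, adjusted p = 5.1e-36), among them Crem at 1.14 ± 0.10 and Plk3 at 1.03 ± 0.10. Heat shock genes rose in 4 of 18 (10 when adjusted over the list alone, median 0.24, adjusted p = 2.7e-14), with Hspb1 at 2.03 ± 0.13. Cytokines and chemokines rose in 7 of 22 (10 when adjusted over the list alone, median 0.31, adjusted p = 6.1e-13). NF-kB response and adhesion genes rose in 7 of 18 (10 when adjusted over the list alone, median 0.48, adjusted p = 2.2e-14). They included Zfp36, which destabilizes cytokine transcripts, at 2.37 ± 0.25 and the prostaglandin synthase Ptgs2 at 2.06 ± 0.24. Unfolded protein response genes rose in 2 of 17, 5 when adjusted over the list alone (median 0.13, adjusted p = 5.5e-08). These 6 calls held with an estimated correlation, the highest adjusted p being 0.0401.

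Other groups were called at 2 h only with the preset correlation. Matrix and proteolysis genes were higher (3 of 19 rose, 5 when adjusted over the list alone, median 0.15; adjusted p = 0.0985 with an estimated correlation), with the protease inhibitor Timp1 at 1.57 ± 0.19 and the protease Adamts1 at 2.21 ± 0.32. Growth factors and neurotrophins were called likewise (2 of 19, 2 when adjusted over the list alone, median 0.14; adjusted p = 0.0860 with an estimated correlation). Cholesterol synthesis genes rose in 1 of 15 (3 when adjusted over the list alone, median 0.18; adjusted p = 0.0954 with an estimated correlation), the riser being Idi1 at 0.76 ± 0.08. Microglia and macrophage markers rose in 2 of 14 (7 when adjusted over the list alone, median 0.24; adjusted p = 0.0832 with an estimated correlation), with the endotoxin co-receptor Cd14 at 0.90 ± 0.18. Striatal neuron markers had a median of 0.49 and oligodendrocyte markers of 0.16, with 0 members of either past the test one by one, over all genes or when adjusted over the list alone (adjusted p = 0.247 and 0.336 with an estimated correlation). The striatal median was 0.24 without sham replicate 1 and ran to 0.64 over the alternative analyses. Hypoxia (1 of 26 rose, median 0.03), apoptosis and p53 (3 of 21, 0.10), antioxidant (1 of 17, 0.05) and oxidative phosphorylation genes (0 of 16, 0.04) had medians near 0 that changed sign in at least 1 alternative (adjusted p = 0.0546, 0.176, 0.0954 and 0.601 with an estimated correlation). Adjusted over the list alone, 4, 5, 2 and 0 of them were higher and 1 apoptosis gene lower. Among them the heme oxygenase Hmox1 rose by 0.84 ± 0.17 and Gadd45g, a stress-induced growth arrest gene, by 1.85 ± 0.17.

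In all, limma called 356 of 28634 probes at 2 h, 257 higher and 99 lower (3320 at an unadjusted p under 0.05), and 96 of them changed at least 2-fold. Within each of the 3 slides that held an array of both groups, 100% of the called probes had the sign of the fit, but those arrays were also part of it. A fit of the 6 arrays alone called 26 probes, with Hspa1a, Cxcl1, Npas4 and Arc still past the test and Fos, Atf3, Bdnf and Ccl3 not, and the fit without the 6 steep arrays called 123.

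At 6 h the same comparison asked how the response had developed. Hspa1a was 104-fold higher than in sham (6.71 ± 0.17, adjusted p = 1.4e-10). Cxcl2 rose by 6.45 ± 0.33, at least 53-fold because no sham array read it above background. Ccl3 was 63.9-fold higher (6.00 ± 0.36), Ccl2 30.4-fold (4.93 ± 0.36) and Atf3 43.7-fold (5.45 ± 0.37), and Cxcl1 rose by 5.12 ± 0.33. Sele, the E-selectin by which activated endothelium holds leukocytes, rose by 4.62 ± 0.51 with 1 of 3 sham arrays above background. Serpinb2, an inhibitor of plasminogen activators, rose by 4.43 ± 0.81, at least 7.20-fold. Il1b was 8.81-fold higher (3.14 ± 0.29), Fos 6.27-fold (2.65 ± 0.31), Arc 2.95-fold (1.56 ± 0.24) and Bdnf 2.66-fold (1.41 ± 0.20). Egr1 (0.20 ± 0.14, adjusted p = 0.459), Gfap (0.38 ± 0.18, 0.228) and Epor (-0.28 ± 0.34, 0.669) did not pass.

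Falls at 6 h were smaller than the largest rises. Degs2 was 3.01-fold lower (-1.59 ± 0.11), Srarp 2.66-fold (-1.41 ± 0.16) and Megf6 2.24-fold (-1.16 ± 0.13). Abcg2, a drug efflux pump of the blood-brain barrier, was 2.35-fold lower (-1.23 ± 0.26). Its partner pump Abcb1a (P-glycoprotein) was at -1.22 ± 0.33, dim (1 of 3 ischemic arrays above background), and called in only 7 of 21 alternative analyses. Adamts13, the protease that trims von Willebrand factor, was at -1.73 ± 0.42 and called in 12 of 21, and Or2v1, an olfactory receptor gene, at -1.29 ± 0.28 and called in 16 of 21. Nxpe1 fell by 1.65 on the log2 scale, at least 2.01-fold since no ischemic array read it above background.

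Inflammatory gene groups were broadly higher at 6 h. NF-kB response and adhesion genes rose in 16 of 18 (also 16 when adjusted over the list alone, median 1.21, adjusted p = 6.1e-25), with the adhesion molecule Icam1 at 2.08 ± 0.15. Cytokines and chemokines rose in 14 of 22, 15 when adjusted over the list alone, which also called 1 lower (median 1.53, adjusted p = 6.0e-18). Matrix and proteolysis genes rose in 14 of 19 (15 when adjusted over the list alone, median 1.2, adjusted p = 1.6e-17), with the proteoglycan Sdc1 at 2.11 ± 0.10 and Timp1 at 2.70 ± 0.19. Interferon response genes rose in 9 of 19 (11 when adjusted over the list alone, median 0.73, adjusted p = 5.2e-11), with Gbp2 at 2.38 ± 0.12 and the chemokine Cxcl10 at 2.92 ± 0.25. Immediate-early genes rose in 18 of 28 (20 when adjusted over the list alone, median 1.14, adjusted p = 3.6e-22), with Myc at 1.52 ± 0.10. Activity-regulated plasticity genes rose in 15 of 27 (16 when adjusted over the list alone, median 0.58, adjusted p = 2.1e-16), with Gadd45b at 2.57 ± 0.19.

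Cell stress groups rose as well. Heat shock genes rose in 11 of 18 (13 when adjusted over the list alone, median 0.42, adjusted p = 1.3e-16), with Hspb1 at 3.44 ± 0.13 and Hsph1 at 1.08 ± 0.09. Unfolded protein response genes rose in 8 of 17 (11 when adjusted over the list alone, median 0.22, adjusted p = 1.6e-12), with the pseudokinase Trib3 at 3.30 ± 0.23 and the transcription factor Ddit3 (CHOP) at 0.84 ± 0.08. Apoptosis and p53 targets rose in 9 of 21 (12 when adjusted over the list alone, median 0.36, adjusted p = 2.3e-12); the members of smallest p were the growth arrest genes Gadd45b and Gadd45g and the anti-apoptotic Mcl1, at 1.11 ± 0.07. Hypoxia targets rose in 9 of 26 (11 when adjusted over the list alone, median 0.16, adjusted p = 2.1e-06), with Hmox1 at 2.95 ± 0.17 and the vasodilator peptide Adm at 2.12 ± 0.16. Growth factors rose in 10 of 19 (11 when adjusted over the list alone, median 0.32, adjusted p = 2.1e-07), with the cytokine Gdf15 at 3.98 ± 0.47 and Hbegf at 2.02 ± 0.17. Antioxidant genes rose in 4 of 17 (5 when adjusted over the list alone, median 0.20, adjusted p = 1.4e-06), with the metallothionein Mt1 at 1.22 ± 0.14. All of these and the inflammatory calls held with an estimated correlation, the highest adjusted p being 0.0175.

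Some groups tied to neurons and vessels held genes that fell. Synaptic transmission genes fell in 8 of 28 (10 lower and 1 higher when adjusted over the list alone, median -0.18; adjusted p = 0.0662 with an estimated correlation), with the sodium channel Scn1a at -0.67 ± 0.09 and the AMPA receptor subunit Gria2 at -0.36 ± 0.07. Neuron markers fell in 3 of 11 (4 when adjusted over the list alone, median -0.14; adjusted p = 0.142 with an estimated correlation), with the cortical transcription factor Neurod6 at -0.81 ± 0.16. Endothelial markers were just short of a call as a group (median -0.35, adjusted p = 0.0542, 0.00902 to 0.158 over the alternative analyses) and were called lower in 7 of 21 of these, such as slide as a random block. One by one, 5 of 12 fell (also 5 when adjusted over the list alone, which called 1 higher). Among these were the transporter Slco1a4 at -1.16 ± 0.13, the angiopoietin receptor Tek at -1.02 ± 0.19 and the tight junction protein Ocln at -0.91 ± 0.16. Mural cell markers fell in 4 of 8 and rose in 1 (5 and 1 when adjusted over the list alone), with Pdgfrb at -0.42 ± 0.09 and Des at 0.82 ± 0.15, and were not called as a group (adjusted p = 0.299). Meningeal markers fell in 2 of 8 (4 when adjusted over the list alone; adjusted p = 0.327 with an estimated correlation). Clock genes fell in 3 of 15, with 1 higher (7 lower and 1 higher when adjusted over the list alone; adjusted p = 0.160 with an estimated correlation), including Dbp at -0.77 ± 0.10 and Per2 at -0.73 ± 0.13.

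Markers of other cell types moved in part. Of 14 microglia and macrophage markers, 3 rose and 2 fell (6 and 2 when adjusted over the list alone; adjusted p = 0.235 with an estimated correlation): Cd14 was at 1.73 ± 0.18, while the markers of resting microglia P2ry12 and Tmem119 were at -0.99 ± 0.21 and -0.66 ± 0.15. Neutrophil markers rose in 2 of 7 (3 when adjusted over the list alone, median 1.08; adjusted p = 0.205 with an estimated correlation), namely the decoy interleukin receptor Il1r2 at 1.77 ± 0.25 and the calcium-binding protein S100a8 at 1.93 ± 0.39. Striatal neuron markers rose in 2 of 9 (6 when adjusted over the list alone, median 0.62; adjusted p = 0.182 with an estimated correlation). Oligodendrocyte markers rose in 2 of 13 (4 when adjusted over the list alone, median 0.27; adjusted p = 0.0973 with an estimated correlation). Cholesterol synthesis genes rose in 5 of 15 (6 when adjusted over the list alone; adjusted p = 0.0662 with an estimated correlation). EPO receptor and JAK-STAT genes rose in 6 of 18 (7 higher and 1 lower when adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), with Stat3 at 0.65 ± 0.10 and Socs3 at 1.1 ± 0.22. Astrocyte (median -0.05), interneuron (0.04), red cell (0.05), lymphocyte (-0.42), choroid plexus (0.47), glucocorticoid response (-0.03) and oxidative phosphorylation genes (-0.02) were not called as groups (adjusted p from 0.0542 to 0.933).

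At 6 h limma called 3164 probes, 1372 higher and 1792 lower (6853 at an unadjusted p under 0.05), and 306 of them changed at least 2-fold; the median over all probes was -0.13. The balance of directions depended on the scaling: quantile normalization gave 1462 higher and 1140 lower, and the authors' values without between-array scaling 849 and 416. On both slides that held an array of each group, 100% of the called probes had the sign of the fit, which those arrays entered, and without the 6 steep arrays, which leaves 1 ischemic array, 202 probes were called.

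**Figure D2:**
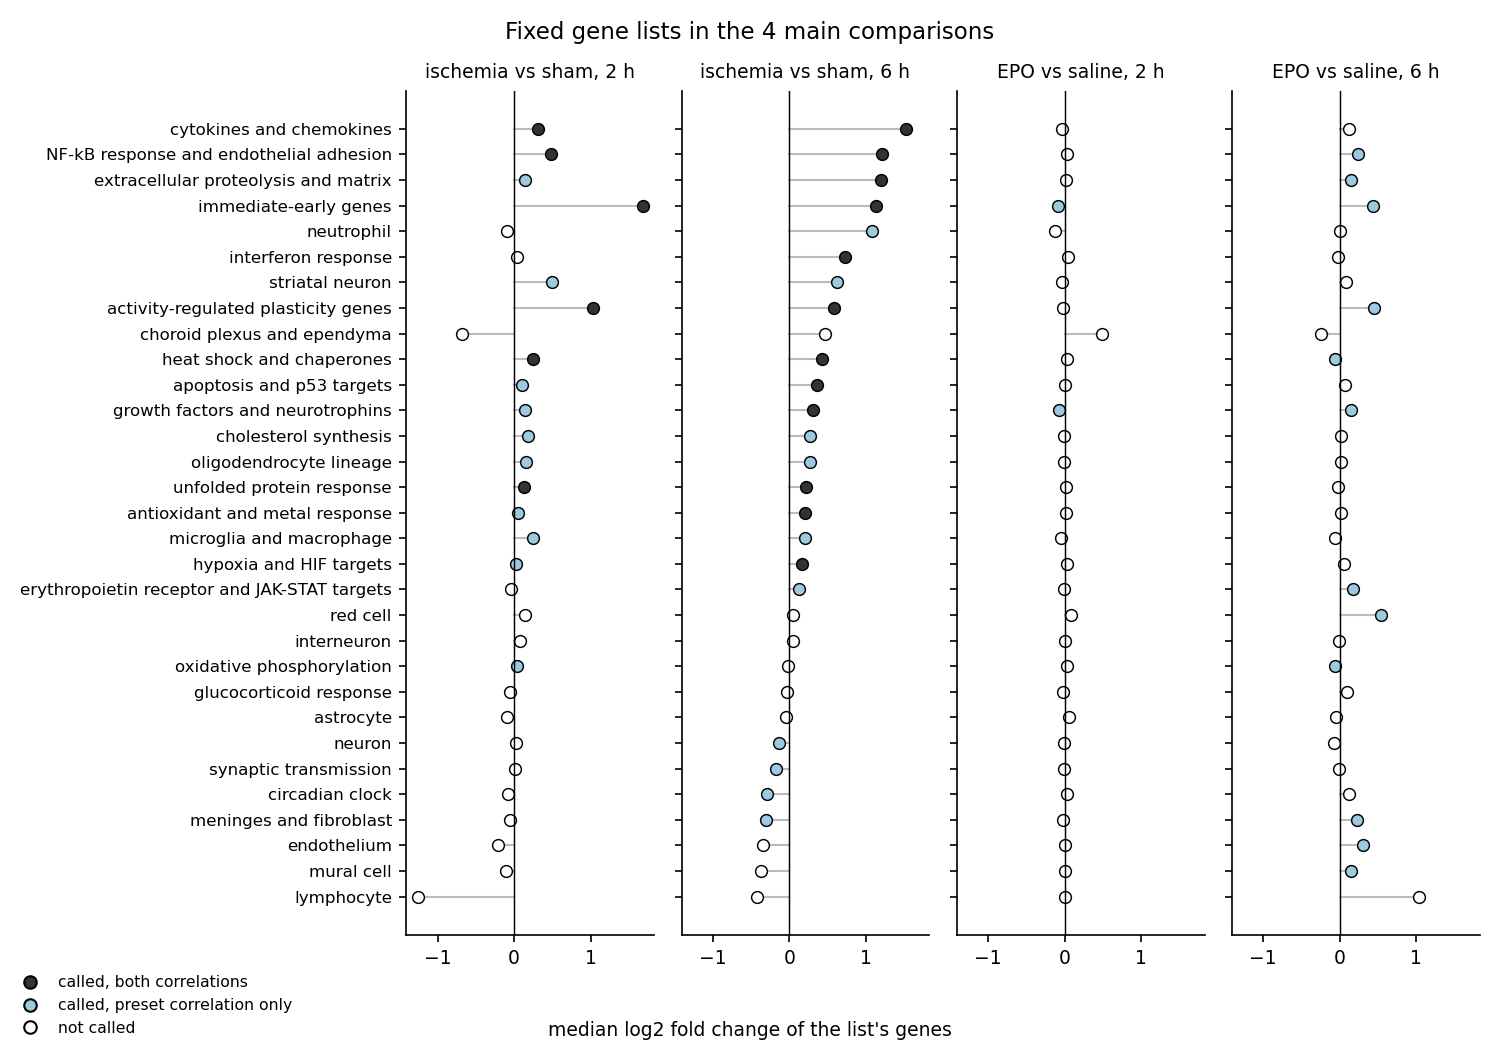
Median log2 fold change (x axis) of the genes of each of the 31 fixed lists (y axis, sorted by the 6 h ischemia comparison) in the 4 main comparisons; dark points were called with the preset and the estimated correlation, blue points with the preset correlation only, and white points were not called. Immediate-early genes are at 1.68 at 2 h and 1.14 at 6 h, cytokines and chemokines at 0.31 and 1.53, and under EPO no list is dark.

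Whether the ischemic change itself differed between the times was tested as an interaction. Among the larger gains by 6 h were 5.29 ± 0.73 for Sele, 4.65 ± 0.96 for the protease inhibitor Serpina3n and 3.58 ± 0.71 for the chemokine Ccl12. The lipid flippase gene Atp8b1 was at 2.69 ± 0.52 and Trib3 at 2.61 ± 0.32. On the other side Abra, an actin-linked activator of transcription, was at -2.26 ± 0.48, the nuclear receptors Nr4a1 and Nr4a3 at -1.72 ± 0.34 and -1.44 ± 0.27, the Fos relative Fosl2 at -1.66 ± 0.24 and Neurod6 at -1.45 ± 0.23. Serpina3n, Abra, Nr4a1 and Atp8b1 passed in 12 of 27, 12 of 28, 16 of 28 and 17 of 27 alternative analyses.

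By group, cytokines and chemokines gained a median of 1.04 between 2 h and 6 h (3 of 22 past the test, 9 higher and 2 lower when adjusted over the list alone; adjusted p = 0.112 with an estimated correlation). Matrix genes gained 0.98 (6 of 19, 10 when adjusted over the list alone), NF-kB response genes 0.74 (3 of 18, 11 when adjusted over the list alone) and interferon response genes 0.64 (3 of 19, 10 when adjusted over the list alone). Their adjusted p were 2.3e-11, 2.3e-11 and 2.7e-11, and all 3 calls held with an estimated correlation. On single slides at 2 h, ischemia gave cytokines 0.13 where the pair differed in spike-in class and 0.78 and 0.65 where it did not. In the same order matrix genes were at 0.02, 0.36 and 0.32 and NF-kB genes at 0.37, 0.80 and 0.64. Interferon genes were at -0.17, -0.01 and 0.15. The part of that pair in the gains of these lists was not tested. Immediate-early genes lost, with a median of -0.56 (6 of 28 fell and 1 rose, 15 and 2 when adjusted over the list alone; adjusted p = 0.301 with an estimated correlation). The test called 410 probes, 233 higher and 177 lower (3479 at an unadjusted p under 0.05). Without the 6 steep arrays it called 0 (1879 at an unadjusted p under 0.05).

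The series was made to ask whether EPO alters the ischemic response. At 2 h after ischemia no gene passed between EPO and saline. Among the smallest p were a higher Bok, a gene of the Bcl-2 family (0.24 ± 0.06), and small shifts in Klhl24 (-0.29 ± 0.08), Sox2 (-0.31 ± 0.09), Ntm (-0.28 ± 0.08), Gpsm2 (0.21 ± 0.06), Mtif2 (0.24 ± 0.07) and Arid5b (-0.32 ± 0.10). The nicotinic receptor subunit Chrna5 (0.88 ± 0.28) leaned higher. The adjusted p was 1.00 for each of these genes. The genes followed throughout differed by less than 2 standard errors: Bdnf was at 0.12 ± 0.20, Arc at -0.34 ± 0.24, Egr1 at -0.04 ± 0.14, Fos at -0.23 ± 0.31, Il1b at 0.00 ± 0.29, Ccl2 at 0.01 ± 0.36, Gfap at 0.32 ± 0.18 and Epor at -0.12 ± 0.34. Immediate-early genes (median -0.09) and growth factors (-0.08) were called slightly lower as groups with the preset correlation (both adjusted p = 0.0172). Of their members 0 passed the test over all genes or when adjusted over the list alone, and both calls were lost (adjusted p = 0.968 with an estimated correlation, fry's adjusted p = 0.970). The other 29 lists were not called. Limma called 0 probes (381 at an unadjusted p under 0.05), as did every alternative analysis. Chance alone gives on average a share of 0.05 of the 28634 probes tested, and 381 is a smaller share, so it shows no excess.

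At 6 h the EPO arrays leaned toward higher activity-regulated genes, although no single gene passed the test over all probes. Fosl2 was 1.87-fold higher with EPO than with saline (0.90 ± 0.17), Mas1, a receptor for angiotensin 1-7, 1.86-fold (0.90 ± 0.17) and Egr1 1.56-fold (0.64 ± 0.14), and Arc was at 0.91 ± 0.24 and Bdnf at 0.87 ± 0.20 (adjusted p = 0.778 for each). Of the 8 tested genes that every comparison gives, the groups did not overlap for Arc, Bdnf, Egr1 and Ccl2, which chance gives for 10% of genes, counting both directions. Arc, Bdnf and Egr1 are also on the plasticity list, written partly from memory of the published study, so this count is not independent evidence. The share over all tested genes was not counted. The muscle-named genes Mustn1 and Actn3 were at 0.39 ± 0.08 and 0.35 ± 0.08, and the lowest by p were Sesn1 (-0.35 ± 0.08), Sephs2 (-0.24 ± 0.06), Cluap1 (-0.29 ± 0.07), Vps37a (-0.32 ± 0.08) and Ssbp3 (-0.21 ± 0.06). Fos was at 0.64 ± 0.31, Epor at 0.46 ± 0.34, Ccl2 at 0.39 ± 0.36, Gfap at 0.31 ± 0.18 and Il1b at 0.05 ± 0.29. Epo itself was above background on 4 of the 18 arrays and Hspa1b on 3, too few to be tested.

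As groups, immediate-early genes had a median of 0.44 with EPO at 6 h, 27 of 28 above 0, and activity-regulated plasticity genes 0.45, 24 of 27 above 0. None passed over all genes; adjusted over the list alone, 10 immediate-early genes were higher, and 12 plasticity genes were higher and 1 lower. The plasticity list was drawn in part from memory of the published study of these samples, so its direction under EPO is not independent evidence. The lists share members such as Arc, Egr1 and Npas4, so they are not separate results, and this limit reaches the immediate-early list in part. Camera called both with the preset correlation (adjusted p = 3.0e-14 and 2.1e-12) but not with an estimated one (adjusted p = 0.242 and 0.0778 with an estimated correlation), and fry gave adjusted p = 0.0422 and 0.0110. Steep arrays numbered 2 of 3 with saline and 1 of 3 with EPO. Between the pairs of arrays on 1 slide, the immediate-early median was 0.81 where the pair differed in spike-in class and 0.16 and 0.26 where it did not, and the plasticity median was 0.65, 0.44 and 0.13.

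Other group shifts with EPO at 6 h were called only with the preset correlation. NF-kB response genes had a median of 0.24, EPO receptor and JAK-STAT targets 0.17, growth factors 0.15, matrix genes 0.15, endothelial markers 0.30, mural cell markers 0.14 and meningeal markers 0.22, with Cebpd at 0.46 ± 0.12, Socs3 at 0.54 ± 0.22 and Vegfa at 0.27 ± 0.10. On single slides, JAK-STAT targets were at 0.46 where the pair differed in spike-in class and 0.21 and -0.05 where it did not. In the same order matrix genes were at 0.54, 0.11 and -0.10 and endothelial markers at 0.60, 0.27 and 0.02. Growth factors were at 0.35, 0.13 and 0.08 and NF-kB genes at 0.38, 0.48 and 0.01. Mural markers were at 0.18, 0.10 and 0.13 and meningeal markers at 0.14, 0.12 and 0.32. The 4 measured red cell genes had a median of 0.54, with the band 3 gene Slc4a1 at 0.88 ± 0.35, the heme synthesis gene Alas2 at 0.55 ± 0.22 and the globin Hbb at 0.53 ± 0.22; 3 of them were higher when adjusted over the list alone. The red cell median was 0.30 without the steep arrays (adjusted p = 0.322, 4.7e-05 to 0.322 over the alternative analyses), and that call was also lost without EPO replicate 3. Oxidative phosphorylation (-0.07) and heat shock genes (-0.06) were lower, but heat shock only in 11 of 21 alternative analyses, and not with the spike-in class as a block (adjusted p = 0.224, 0.00119 to 0.820 over the alternative analyses). With an estimated correlation none of these 10 was called (adjusted p = 0.311 to 0.509 with an estimated correlation); over all genes 0 members passed, and adjusted over the list alone 1 NF-kB gene and 1 growth factor were higher and 0 members of the other lists apart from red cell. Limma called 0 probes (1184 at an unadjusted p under 0.05, smallest adjusted p 0.778), as did every alternative analysis. Of the 28634 probes tested, 1184 is a smaller share than the 0.05 that chance alone gives on average, so it shows no excess.

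**Figure D3:**
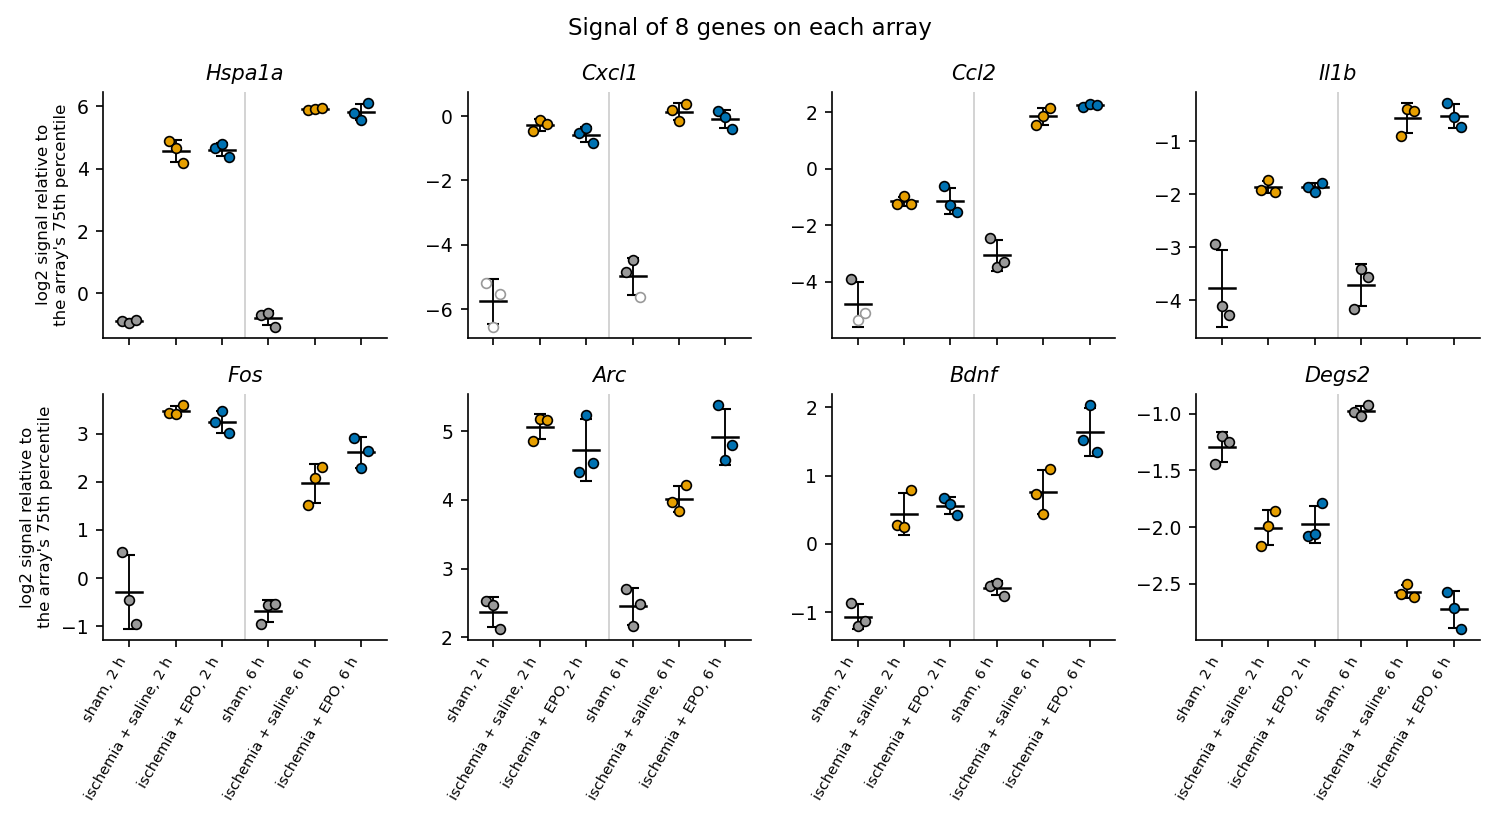
Signal of 8 genes on each array (y axis, log2 relative to the array's 75th percentile) in the 6 groups; each point is 1 array, open points were not well above background, the bar is the group mean and the whiskers its SD (n = 3). Hspa1a, Cxcl1, Ccl2 and Il1b sit far above sham in both ischemic groups, Degs2 below, and Arc and Bdnf sit higher with EPO than with saline at 6 h by 0.91 and 0.87, differences that did not pass over all probes.

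**Figure D4:**
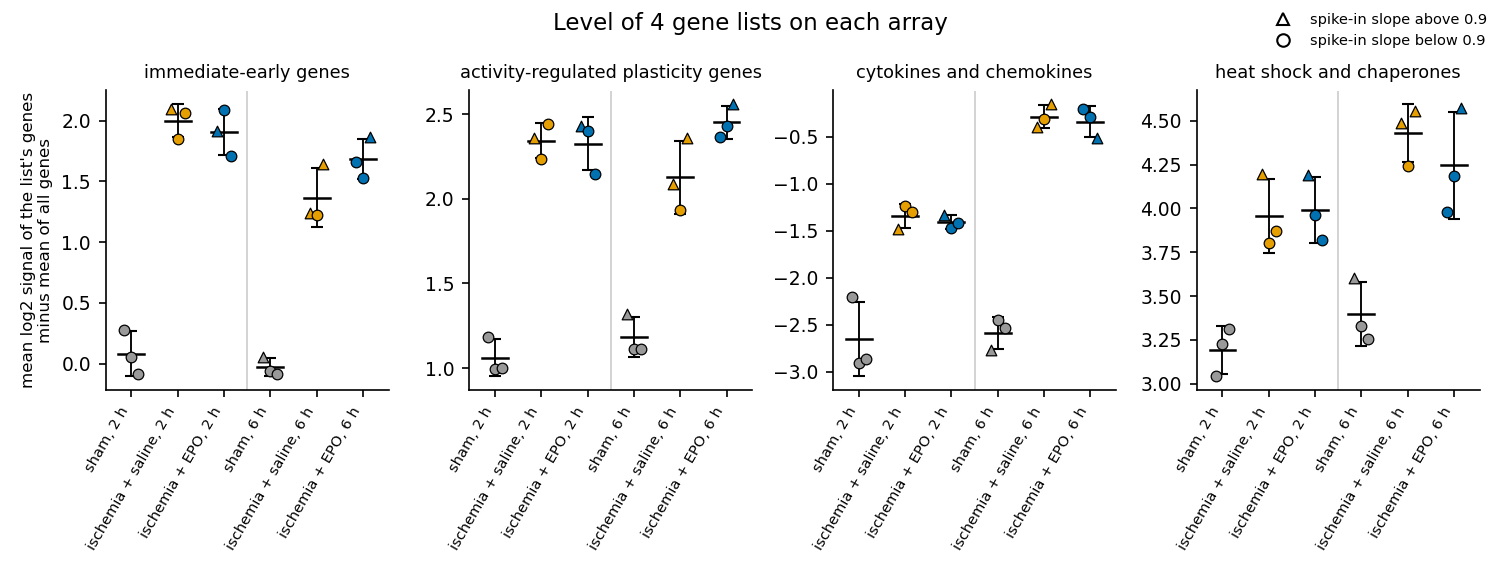
Mean log2 signal of the genes of 4 lists minus the mean of all genes (y axis) on each array in the 6 groups; triangles are arrays with a spike-in slope above 0.9, bars are group means and whiskers SDs (n = 3). At 6 h the immediate-early level is 1.22 to 1.64 with saline and 1.53 to 1.86 with EPO, so the groups overlap, and both lie above sham, at -0.08 to 0.06.

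Whether the EPO effect differed between 6 h and 2 h was tested in the same way. Fosl2 (0.91 ± 0.24), Mas1 (0.92 ± 0.24), Mustn1 (0.42 ± 0.11) and Arhgap45 (0.36 ± 0.09) led among the higher values. Chrna5 (-1.34 ± 0.40), C10h5orf15 (-1.15 ± 0.26), Rfc3 (-0.56 ± 0.16), Cluap1 (-0.50 ± 0.10) and Sephs2 (-0.31 ± 0.09) led among the lower. None passed the test (adjusted p = 0.920 for each). Immediate-early genes had a median difference of 0.52 and plasticity genes of 0.44, with 6 and 4 higher when adjusted over the list alone and 0 over all genes (adjusted p = 0.135 and 0.121 with an estimated correlation, fry's adjusted p = 0.103 for both). Limma called 0 probes (668 at an unadjusted p under 0.05), and leaving out the third saline array at 2 h gave 1. Again 668 is a smaller share of the 28634 probes tested than the 0.05 that chance alone gives on average.

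EPO-treated ischemic cortex was also set against sham. The same families led. At 2 h Hspa1a was at 5.50 ± 0.17, Cxcl2 at 5.36 ± 0.33 (at least 15.0-fold), Cxcl1 at 5.18 ± 0.33 (at least 15.8-fold), Ccl3 at 5.07 ± 0.36 and Atf3 at 4.73 ± 0.37. Lower were Sox18 (-0.99 ± 0.14), Srarp (-0.98 ± 0.16) and Dido1 (-0.95 ± 0.18). Zfp36l3 (-1.17 ± 0.26) and Fmo2 (-0.87 ± 0.20) passed in only 10 of 22 and 5 of 22 alternative analyses. At 6 h Hspa1a was at 6.62 ± 0.17, Cxcl2 at 5.84 ± 0.33 (at least 34.8-fold), Ccl3 at 5.79 ± 0.36, Serpinb2 at 5.59 ± 0.81 (at least 16-fold) and Atf3 at 5.46 ± 0.37. Degs2 fell by 1.75 on the log2 scale, and the neuropeptide Y receptors Npy5r and Npy1r by 1.31 and 1.27; Tyr (-1.39 ± 0.33) and Abcb1a (-1.30 ± 0.33) were below background on every EPO array, so at least 1.60-fold and 1.43-fold lower. Limma called 382 probes at 2 h (287 higher, 95 lower) and 4615 at 6 h (1869 higher, 2746 lower); with only the 6 arrays of each comparison it called 3 and 1168.

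Probes called in ischemia with saline were often called the same way with EPO: 79.2% of 356 at 2 h and 86.3% of 3164 at 6 h. With slide as a fixed block the share at 2 h was only 36.5%. At 2 h, 224 higher and 58 lower probes were shared, where independent lists would share 2.58 and 0.328. At 6 h, 1253 and 1476 were shared, against 89.6 and 172. Both comparisons use the same sham arrays. The simulation drew unchanged groups and a shared sham group at random from the residuals of all arrays. It kept neither the real sham arrays nor the times nor the layout of the spike-in classes. Such groups shared 0 calls in 20 runs, but unchanged groups have few calls to share, so this sets no baseline. Their changes correlated across probes at 0.445 and 0.435 in separate draws. In the data the correlation was 0.941 at 2 h and 0.50 at 6 h. The covariance was 0.215 at 2 h, beside 0.0841 simulated, and 0.0839 at 6 h, beside 0.0864. The sham arrays were not split between the comparisons, so part of the overlap may come from sharing them. The spike-in classes were also uneven. At 2 h sham held 0 steep arrays and each ischemic group 1, and at 6 h saline held 2 and sham and EPO 1 each. The correlations were not repeated with the class as a block, so its part in 0.941 and 0.50 was not tested.

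A treatment that reverses the ischemic change would lower the genes that ischemia raised. This was tested on separate animals, with the genes called at each time examined under EPO at the other. Some of these genes were not called in ischemia at the other time, such as Egr1 at 6 h and Sele at 2 h. The test therefore cannot decide whether EPO reverses ischemic changes of the same time. Of 159 genes that ischemia raised at 2 h, which include Hspa1a, Cxcl1, Fos and Arc, 33 (20.8%) were lower with EPO at 6 h. Most thus leaned further up, with a median of 0.14 (adjusted p = 4.5e-14, adjusted p = 0.0793 with an estimated correlation, fry 0.0180). These genes include the immediate-early and plasticity genes called at 2 h, and the EPO and saline arrays at 6 h are the same. The lean is therefore not separate evidence from those lists. Steep arrays numbered 2 with saline and 1 with EPO there. Of 43 genes that ischemia lowered at 2 h, such as Sox18 and Degs2, 15 (34.9%) were higher with EPO at 6 h, with a median of -0.05, a call made in 17 of 27 alternative analyses (adjusted p = 0.0212, 7.8e-04 to 0.760 over the alternative analyses; adjusted p = 0.255 with an estimated correlation, fry 0.574). Of the genes called at 6 h, 42.5% of 765 raised and 54.0% of 844 lowered ones moved the opposite way with EPO at 2 h (adjusted p = 0.466 and 0.666). Over all genes the shares with these signs were 42.7% lower at 6 h and 46.9% at 2 h, so no reversal by EPO across the times was detected with all arrays. For the genes lowered at 6 h this rests on single arrays: without saline replicate 1 at 2 h 61.5% were opposite, a call toward reversal (adjusted p = 0.00115), and without replicate 2 47.8%, a call the other way (adjusted p = 0.0345, 0.00115 to 0.966 over the alternative analyses).

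Sham animals at 6 h were set against sham animals at 2 h to see what differed between the times without ischemia. Time was not isolated: sham at 6 h held 1 steep array, scanned on the second day, and sham at 2 h held 0. Tnfrsf11b, the decoy receptor osteoprotegerin, was higher at 6 h by 1.55 ± 0.14, the splicing kinase Clk1 by 1.1 ± 0.14, the transcription factor Hhex by 1.06 ± 0.09 and Lonrf3 by 1.03 ± 0.11. The flow-responsive endothelial genes Klf2 and Apold1 were lower, at -1.07 ± 0.15 and -1.08 ± 0.21, as were Gadd45g (-1.06 ± 0.17), Tmem252 (-1.17 ± 0.24) and Zfp36l3 (-1.43 ± 0.26). Slpi, a protease inhibitor, was at 1.82 ± 0.34, but its other probe had the opposite sign, and it passed in 8 of 22 alternative analyses. Cholesterol synthesis genes (median -0.20), endothelial (0.33) and mural markers (0.19) were called with the preset correlation only (adjusted p = 0.683 for each with an estimated correlation), with 0 members past the test over all genes and, adjusted over the list alone, 4 cholesterol genes lower and 2 endothelial and 1 mural markers higher. Limma called 138 probes, 89 higher and 49 lower; the count was 3 with slide as a fixed block and 0 without the steep arrays or with only the 6 arrays of the comparison (2080 and 2311 at an unadjusted p under 0.05).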

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

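The regrouping of the time labels within treatment and the fits with the spike-in class or slope were chosen only after the result was seen; the other regrouping was planned. The results below stand out because the change from sham to ischemia differed between 2 h and 6 h by a test of the difference itself. It differed for 410 probes, 233 higher at 6 h and 177 lower.

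For the genes named by the rule, the differences were 5.29 for Sele (-0.66 at 2 h, 4.62 at 6 h), 4.65 for Serpina3n (-0.70 at 2 h, 3.94 at 6 h) and 3.58 for Ccl12 (-0.59 at 2 h, 2.99 at 6 h). They were 2.69 for Atp8b1 (-0.89 at 2 h, 1.80 at 6 h) and 2.61 for Trib3 (0.69 at 2 h, 3.30 at 6 h). On the other side they were -2.26 for Abra (2.60 at 2 h, 0.34 at 6 h), -1.72 for Nr4a1 (2.26 at 2 h, 0.55 at 6 h) and -1.66 for Fosl2 (1.93 at 2 h, 0.27 at 6 h). The last were -1.45 for Neurod6 (0.64 at 2 h, -0.81 at 6 h) and -1.44 for Nr4a3 (1.5 at 2 h, 0.06 at 6 h). Sele, Serpina3n, Ccl12 and Atp8b1 were not called at 2 h, so their negative values there are no falls.

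Among gene lists, the median difference was 1.04 for cytokines and chemokines, 0.98 for matrix and proteolysis, 0.74 for NF-kB response, 0.64 for interferon response and 0.47 for apoptosis and p53. It was 0.24 for growth factors, 0.22 for heat shock, 0.16 for unfolded protein response, 0.15 for hypoxia and 0.13 for antioxidant genes. It was -0.56 for immediate-early genes, -0.21 for synaptic transmission, -0.14 for neuron markers and -0.29 for mural cell markers. With an estimated correlation the calls of matrix, NF-kB response, interferon response, apoptosis, unfolded protein response, hypoxia, antioxidant and synaptic genes held. Those of cytokines (adjusted p = 0.112 with an estimated correlation), growth factors (0.0964), heat shock (0.0979), immediate-early genes (0.301), neuron (0.0991) and mural cell markers (0.301) did not. Synaptic genes included 0 past the test over all genes and 5 lower when adjusted over the list alone; apoptosis genes included 6 past it and 11 higher when adjusted over the list alone. Plasticity genes (median -0.16), JAK-STAT targets (0.24), neutrophil (0.77), oligodendrocyte (0.14) and choroid plexus markers (0.83) were called with the preset correlation only (adjusted p = 0.167 to 0.433 with an estimated correlation).

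Whether chance can give a count like 410 was examined by regrouping the arrays. Among 100 drawn splits of the same arrays, 7 gave at least as many calls, the real one included, and the highest other gave 1284. Chance was not excluded by this test. All 6 others as large kept the real 6 h groups, as 9 of the drawn splits did in all. When only the times were regrouped within sham and within ischemia, 4 of 100 splits gave as many, the highest other 1614, and the 3 others kept the times of the ischemia arrays or exchanged them whole. That share lies just under 0.05, and since both kinds of split retain part of the real difference, a difference between the times may stand behind all of them, which these splits cannot separate from chance. The design names time after surgery as the biological difference, which was not tested further. The count was 568 with the spike-in class as a block and 484 with the slope as a covariate. Without the 6 steep arrays, which leaves 1 ischemia array at 6 h, limma called 0 probes (1879 at an unadjusted p under 0.05).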

How the results depend on the processing

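The fits that use the spike-in slope (its class as a block, the slope as a covariate, and no steep arrays) were chosen only after the data were seen. Named genes kept their side of the threshold in 6297 of 6883 values, weakened in 515 and strengthened in 71. Lists kept theirs in 2443 of 2604 values, with 96 weaker, 63 stronger and 2 reversed. Direction was compared only where the first fit or the alternative made a call, and no named gene reversed there. Values uncalled in both fits may have changed sign. The EPO comparisons had 0 limma calls at each time in every alternative. With counts that stayed at 0, as for EPO, taken as unchanged, counts stayed within 1.5 times the first value in 160 of 219. Those that did not are given here for ischemia against sham at 2 h and 6 h, EPO-treated ischemia against sham at 2 h and 6 h, sham over time, and ischemia by time. The authors' values without scaling gave 172, 1265, 171, 2255, 25 and 230. A change of at least 2-fold gave 96, 306, 86, 454, 21 and 124, since fewer probes can pass. Without the 6 steep arrays, which leaves 12 arrays and 1 ischemia array at 6 h assumed to vary like the others, the counts were 123, 202, 140, 2237, 0 and 0 (at an unadjusted p under 0.05, 2080 and 1879 for the last pair). Only the groups compared, with 4 residual degrees of freedom, gave 26, 1343, 3, 1168 and 0 (2311 at an unadjusted p under 0.05 for the last). No filter gave 2093 for ischemia at 6 h, 251 for EPO-treated ischemia at 2 h, 60 for sham and 218 for ischemia by time; 1 probe per gene, with fewer tests, gave 1844 and 2627 at 6 h. Slide as a random block gave 634 for ischemia at 2 h, 214 for sham and 756 for ischemia by time, and slide as a fixed block 125 for EPO-treated ischemia at 2 h and 3 for sham. The sham count was 80 with the replicate block, 210 with probes well above background on all arrays, 66 without the 2 arrays titled apart and 85 with the slope as a covariate. Apart from the reasons given, the cause was not tested.

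The share of genes lowered by ischemia at 2 h that were higher with EPO at 6 h lost its call with normexp background correction, 44.1% (adjusted p = 0.0636), and quantile normalization, 41.0% (adjusted p = 0.501). It did so with slide as a fixed block, 44.8% (adjusted p = 0.221), the slope class as a block, 46.4% (adjusted p = 0.108), and without the steep arrays, 50% (adjusted p = 0.760). Over all alternatives the adjusted p ran from 7.8e-04 to 0.760. The overlap at 2 h was 36.5% with slide as a fixed block. Oxidative phosphorylation genes at 2 h turned to -0.028 with quantile normalization, and oligodendrocyte markers under EPO at 6 h, uncalled and just below all genes before, to 0.21 without the steep arrays. The cause was not tested. The median of all probes moved by more than 0.1 with the authors' values in EPO-treated ischemia at 2 h (-0.18, -0.07 before) and in ischemia by time (0.11, -0.01 before). It did so with no filter under EPO at 6 h (0.16, 0.05 before) and in EPO by time (0.17, 0.06 before), and in EPO-treated ischemia at 6 h without EPO replicate 1 (-0.10, 0.00 before).

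With 1 array left out the counts ran from 217 to 314 (ischemia, 2 h), 1749 to 2227 (ischemia, 6 h), 204 to 320 (EPO-treated ischemia, 2 h), 3145 to 4393 (6 h), 40 to 57 (sham over time), 198 to 335 (ischemia by time) and 0 to 1 (EPO by time). Each sham array lowered the sham count more than 1.5 times when left out. At 2 h the ischemia count fell that far without sham replicate 2 (220) or saline replicate 3 (217), and the EPO-treated count without sham replicate 2 (229) or EPO replicate 2 (204). At 6 h the ischemia count did so without sham replicates 2 or 3 (2057 and 1904) or saline replicates 2 or 3 (2055 and 1749). The ischemia by time count did so without sham replicate 1 or saline replicates 1 or 3 at 2 h (270, 229 and 222) and without sham replicate 3 or saline replicates 2 or 3 at 6 h (225, 239 and 198). The opposite shares ran from 36.6 to 44.8% and 47.8 to 61.5% for genes raised and lowered at 6 h. They ran from 14.7 to 31.7% and 26.7 to 50% for genes raised and lowered at 2 h. For genes lowered at 6 h, uncalled with all arrays, leaving out saline replicate 1 at 2 h gave 61.5% (adjusted p = 0.00115) and leaving out saline replicate 2 reversed the direction at 47.8% (adjusted p = 0.0345), within a range of 0.00115 to 0.957. Genes raised at 6 h gave 39.1% without EPO replicate 3 at 2 h (adjusted p = 0.0175, range 0.0175 to 0.945). The call for genes lowered at 2 h ended without sham replicate 2 or 3 or saline replicate 2 at 2 h (50%, 45.8% and 46.4%), or saline or EPO replicate 1 at 6 h (40.6% and 43.9%). The overlaps ran from 62.5 to 90.3% at 2 h and 73.2 to 93.7% at 6 h. Fewer arrays give less precision, which the left-out fits share by construction. Signal over background limits the rest: 23142 of 41012 probes were well above background on all 18 arrays.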

Other observations

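The tests of the 3 patterns weighed below, and the regrouping of the time labels for EPO, were chosen only after the result was seen; the other splits were planned. In EPO-treated ischemia at 6 h, immediate-early genes rose against sham in 24 of 28 (28 when adjusted over the list alone, median 1.51), plasticity genes in 20 of 27 (23 when adjusted over the list alone, median 1.09) and NF-kB response genes in 17 of 18 (18 when adjusted over the list alone, median 1.62). Striatal neuron markers rose in 7 of 9 (also 7 when adjusted over the list alone; adjusted p = 0.193 with an estimated correlation). Oligodendrocyte markers rose in 4 of 13 (7 when adjusted over the list alone; adjusted p = 0.159 with an estimated correlation). Neuron markers fell in 4 of 11 (also 4 when adjusted over the list alone; adjusted p = 0.0804 with an estimated correlation). Glucocorticoid response genes rose in 4 and fell in 3 of 14 (5 and 3 when adjusted over the list alone). Endothelial markers rose in 1 and fell in 5 of 12 (2 and 5 when adjusted over the list alone). Neither group was called (adjusted p = 0.0895 and 0.494).

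At 2 h, clock genes fell in 3 of 15 with ischemia (2 higher and 4 lower when adjusted over the list alone). Glucocorticoid response genes rose in 2 of 14 (4 higher and 3 lower when adjusted over the list alone). Neither group was called (adjusted p = 0.359 and 0.250). Synaptic (median 0.01), interferon (0.04), JAK-STAT (-0.04), neuron (0.03), interneuron (0.08), astrocyte (-0.10), neutrophil (-0.09), endothelial (-0.21), mural (-0.11), red cell (0.15), meningeal (-0.05), choroid plexus (-0.69) and lymphocyte genes (-1.26) were not called then either (adjusted p from 0.126 to 0.595). The 7 lymphocyte and 6 choroid plexus markers had wide scatter and 0 calls in limma in each of the 9 comparisons, over all genes or when adjusted over the list alone. On single slides at 2 h, neutrophil markers were at -0.63 where the pair differed in spike-in class and 0.80 and 0.37 where it did not. The neutrophil median of -0.09 is therefore no fall. In the same order lymphocyte markers were at -4.37, 0.28 and -0.33 and endothelial markers at -0.50, -0.12 and -0.004.

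Immediate-early and activity-regulated genes leaned higher with EPO than with saline at 6 h, with a median of 0.39 over 47 genes of the joined lists. The second list is not independent evidence, and the first shares members with it, such as Arc and Egr1. Against a difference in spike-in class as the whole cause, the median was 0.35 (standard error 0.10, 0.02 for all genes) with the class as a block. Against 1 array as the cause, the lowest value with an array left out was 0.28 (highest 0.42), without replicate 1 of EPO. Against a larger ischemic response of all genes, the 284 measured genes of the 16 other pathway lists lay at -0.049 relative to all genes, where 0.16 would be needed (standard error of the difference 0.06), and with the class as a block at 0.00 against 0.19 (0.06), though some lists, such as JAK-STAT targets, reached their share (0.12 against 0.08). As a hypothesis, EPO may prolong or strengthen activity-dependent transcription at 6 h, but with an estimated correlation neither list was called (adjusted p = 0.242 and 0.0778 with an estimated correlation), the pattern was found and tested on the same 6 arrays, and chance stays open.

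Endothelial markers were lower at 6 h of ischemia in 5 of 12 cases. A loss of endothelial cells would lower them alike, but 5 of all 12 differed from the median of the 12 (-0.35) by more than 2 standard errors of the difference, 1 above it and 4 below. That argues against an even loss as the whole cause, and a loss together with other changes stays open. With the spike-in class as a block, 5 markers were again called lower, which argues against the class as the whole cause. The sham arrays at 6 h lay above those at 2 h for these markers (median 0.33; adjusted p = 0.683 with an estimated correlation), so the reference may carry part of the difference, and a change of transcription within endothelial cells stays an untested hypothesis.

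Striatal neuron markers were higher in ischemia, with a median of 0.62 at 6 h, but were not called at either time with an estimated correlation (adjusted p = 0.247 at 2 h and 0.182 at 6 h with an estimated correlation). The spike-in class as a block gave 0.71 (standard error 0.19, -0.05 for all genes), and leaving out the steep arrays gave 0.34 (adjusted p = 0.0287, 3.4e-06 to 0.0287 over the alternatives). The class is thus not the whole cause by the block, but it may carry part of the rise. More striatal tissue in the ischemic samples would raise all the markers, each by what a small share of striatum can give it, so not by 1 common amount. By the test 1 of the 9 markers lay below their median by more than 2 standard errors of the difference at 6 h and 0 at 2 h. More striatal tissue could not be excluded by this test and was not told apart from a change within cortex. The filter required every tested gene to be above background in at least 1 group, so the detection of all 9 does not help here.

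Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real split was the only 1 as large for ischemia against sham at 2 h (356 probes, highest other 0) and 6 h (3164, 0), EPO-treated ischemia against sham at 2 h (382, 0) and 6 h (4615, 0) and sham over time (138, 0). Where the real count is 0 every split is as large by construction, so the splits decide nothing for EPO. Between EPO and saline these were 10 of 10 at each time, the highest other 2 at 2 h and 0 at 6 h (381 and 1184 probes at an unadjusted p under 0.05 in limma for the real ones). Both 381 and 1184 are smaller shares of the 28634 probes tested than the 0.05 that chance alone gives on average. For EPO by time the splits as large were 100 of 100 drawn splits and 100 of 100 with the times alone regrouped. The highest others called 6669 and 6456 probes, which points to a structure of the arrays. Of the drawn splits for EPO by time, 2 gave more than 100 calls, and 2 of these set steep against other arrays in opposite directions at the different times. For ischemia by time 0 of 9 such splits did.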
